A study of Bos taurus with 16 samples.

How the data were processed

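RNA was sequenced from 16 day 19 bovine conceptuses, the elongated embryos with their trophoblast, from which the embryonic disc had been taken off. Per the labels, 7 conceptuses came from dry cows and 5 from lactating cows, all of which had received 1 embryo on day 7, and 4 came from maiden heifers bred by artificial insemination. The transferred embryos came from superovulated maiden heifers inseminated with semen of the same sire. Recipient cows were synchronised about 65 to 75 days after calving. Libraries were made with the NuGEN Encore kit from 150 ng of total RNA extracted with Trizol.

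The values used are those the authors deposited, a table of 31903 genes by 16 samples on a log2 scale. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.0.13 and DESeq2, and the label of the table gives its values as regularized log2 (rlog) values of DESeq2, computed by the authors. These are counts normalised for library size and shrunken towards the mean of each gene, most strongly at low counts, so differences of weakly expressed genes are understated. The genome build, annotation, counting tool and strandedness are not given in the sources used here. The values carry no counts, so the depth of each library is unknown and no counting interval is given; precision is given as the spread between conceptuses. Of the gene names, 20250 matched a current RefSeq symbol, a further 629 matched a synonym, 14646 were LOC identifiers and 13 had been turned into dates; gene names are printed as the table gives them. Members of gene families with near-identical copies, such as pregnancy-associated glycoproteins, prolactin-related proteins, interferon tau and histones, share reads, and the values of single members are uncertain for that reason.

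Genes at 0 in every sample (3330) were left out, as were genes with a mean rlog value under 3 over all samples, which left 13160 genes, 2121 of them with LOC names. No further scaling was applied. Group means were fitted to all 16 samples with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a trend of the variance on the mean and no covariates. The contrasts were lactating against dry, lactating against heifer and dry against heifer, with a moderated F test over the 3 groups. P values were two-sided and adjusted by the method of Benjamini and Hochberg within each contrast, and a gene was called at an adjusted p below 0.05. Every log2 difference is the mean of the group named first minus the mean of the group named second, with intervals at 95%.

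A set of 41 gene lists covering cell types, trophoblast products, metabolic and stress pathways, RNA quality and conceptus sex was written from general knowledge. Of these, 38 had at least 3 tested members and were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists within a contrast. The same test with an estimated correlation and limma's fry test are given beside it. Per list, members were also adjusted over the list alone. Mitochondrially encoded genes, adult blood genes and XIST had too few tested members and were not tested as lists.

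Genes were named by a rule: up to 12 called genes per direction, filled up to 5 per direction with the genes with a symbol that had the smallest p where fewer were called, up to 4 members with the smallest p of each list called by camera, and 14 anchor genes, of which 13 were tested. Some genes that met this rule are not reported here. The lists, the rule, the contrasts, the tests, the filter and the alternatives, apart from 3 added later, were fixed before the data were examined. A few further genes, named for single libraries that stood apart, were chosen after their values were seen, as was a combined binucleate score, the mean over the binucleate-clade glycoprotein and prolactin lists.

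Separation of the groups was measured as the share of the total squared Euclidean distance over the tested genes that lay between groups, and spread within groups as the distance of each conceptus to the mean of the others in its group. Both were tested by exact enumeration of the group labels (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0), and figures were drawn with matplotlib 3.10.9. List scores are the mean over the tested members of a list after centring each gene on its mean over all samples. Correlations between scores were tested with 100000 permutations, or exactly in the 7 dry conceptuses.

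The tests were checked on simulated data: shifts were added to 200 of the 13160 genes after shuffling residuals, in 10 draws. The shifts were added to rlog values, which are already shrunken. The shares can therefore overstate how often a change of that size before shrinkage would be called, most at low counts. For lactating against dry, limma called 36.65% of genes shifted by 0.5 log2 units, 87.85% of those shifted by 1 and 98.25% of those shifted by 2. For lactating against heifer the shares were 22.3%, 84.45% and 97%, and for dry against heifer 27.95%, 87.7% and 97.25%.

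The alternatives tried were no filter on expression, a minimum mean of 6, median centring, quantile normalisation, sample weights, no variance trend, robust moderation, the number that opens each sample title as a factor, a conceptus sex marker as a covariate, an adjusted p below 0.1, camera on ranks, camera with an estimated correlation, fits of the compared groups alone, gene scaling and the 500 most variable genes for the distances, and leaving out each conceptus in turn. The 3 alternatives chosen after seeing the data were the removal of 3 libraries that stood apart (lactating replicate 4, dry replicate 6 and heifer replicate 4), exact permutation of list scores, and a comparison of all 12 cow conceptuses with the 4 heifer conceptuses. Lactating replicate 1 was kept in that removal although it also lay far from the rest. In it 46 genes lay more than 1 log2 unit below every other library and 13 above. Its mean correlation with other libraries was 0.973, against 0.980 for lactating replicate 4 and 0.979 for heifer replicate 4. Counts of genes at an unadjusted p below 0.05 were added as a result after no gene was called. Replicate numbers follow the order of the records only.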

Results

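Transcript levels were measured by RNA sequencing in 16 bovine conceptuses recovered on day 19, around the start of implantation, 7 from dry cows, 5 from lactating cows and 4 from maiden heifers. Both cow groups carried transferred embryos of the same origin, and the heifers had conceived after artificial insemination. The values are regularized log2 (rlog) values of 31903 genes, of which 13160 were tested. The depth of each library is unknown, since the table holds no counts.

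Transcripts known from elongating trophoblast were abundant in all groups. Interferon tau (IFNT2), the signal by which the ruminant conceptus maintains the corpus luteum, averaged 15.0 ± 0.63 (SD, n = 5) in lactating, 14.9 ± 0.60 (SD, n = 7) in dry and 14.4 ± 0.40 (SD, n = 4) in heifer conceptuses. PAG2, a pregnancy-associated glycoprotein of mononucleate trophoblast, averaged 14.4 ± 0.60, 14.9 ± 0.37 and 14.9 ± 0.29 in the same groups. PTGS2, a prostaglandin synthase, averaged 14.8 ± 0.55, 14.6 ± 0.45 and 14.1 ± 0.22. Y-linked genes averaged 7.83 to 8.13 in 6 libraries (lactating replicates 1 and 3, dry replicates 3, 6 and 7, and heifer replicate 2) and 3.78 to 4.35 in the other 10. XIST, the transcript of the inactive X chromosome, lay at 12.6 to 13.1 in those 10, at 8.38 to 8.97 in 5 of the 6, and at 10.3 in dry replicate 6.

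**Figure D1:**
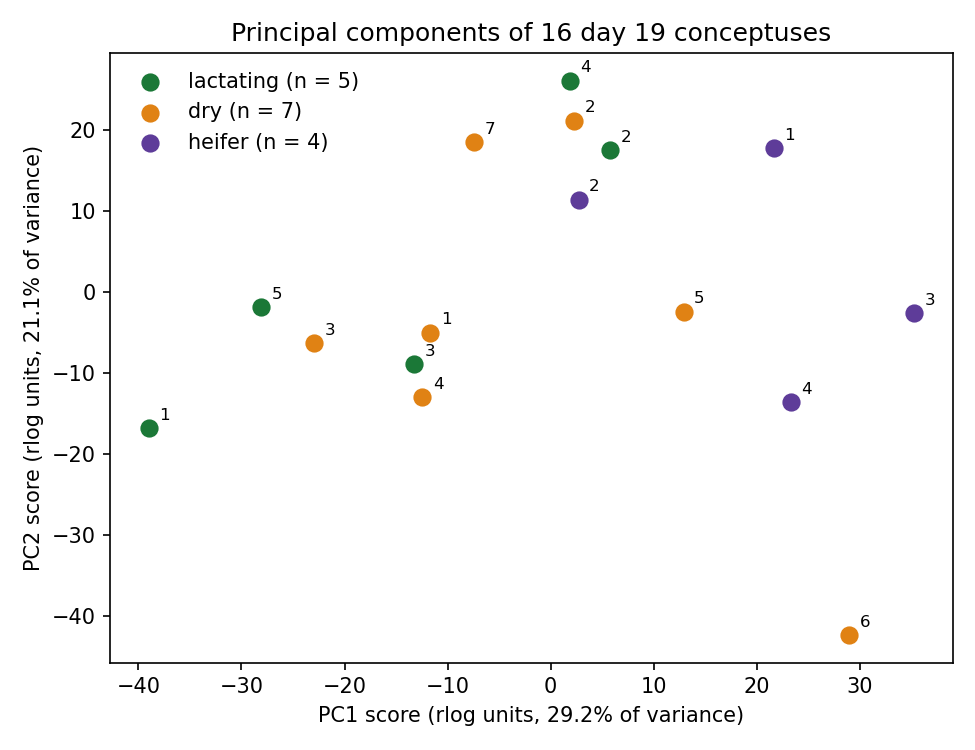
Scores of the 16 conceptuses on the first principal component (x axis, rlog units, 29.2% of the variance) and the second (y axis, rlog units, 21.1%), each point a conceptus labelled by its replicate number and coloured by group. Lactating and dry conceptuses overlap, and dry replicate 6 lies apart from the rest with a PC2 score of -42.3.

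No separation of lactating from dry conceptuses was detected: the groups accounted for 8.51% of the squared distance between the 12 conceptuses (exact permutation p = 0.504, adjusted p = 0.504). Lactating and heifer conceptuses had 26.1% between them (exact permutation p = 0.0476, adjusted p = 0.124) and dry and heifer conceptuses 14.7% (exact permutation p = 0.118, adjusted p = 0.158). For all 3 groups the share was 19.4% (exact permutation p = 0.0619, adjusted p = 0.124). The mean distance of a conceptus to the others of its group was 41.9 ± 7.47 (SD, n = 5) for lactating, 40.3 ± 10.7 (SD, n = 7) for dry and 41.0 ± 2.44 (SD, n = 4) for heifer conceptuses, and no difference between groups was detected (exact permutation adjusted p = 0.948 for each). Over the 3 groups, limma's F test called 0 genes, with 1626 at an unadjusted p below 0.05 and 658 expected by chance. Without heifer replicate 3 the count at unadjusted p was 757.

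The comparison of lactating with dry cows addresses the effect of lactation in the recipient on the conceptus. WNT2B, a Wnt ligand, averaged 5.38 ± 1.00 (SD, n = 5) in lactating and 4.17 ± 0.30 (SD, n = 7) in dry conceptuses, a log2 difference of 1.20. MYL7, a myosin light chain, averaged 6.22 ± 0.82 and 4.998 ± 0.456, a difference of 1.22. UGT1A1, a glucuronosyltransferase, averaged 5.62 ± 0.18 and 6.09 ± 0.20, a difference of -0.47. PRKAA2, a catalytic subunit of the energy sensor AMP-activated protein kinase, differed by -0.50. The other genes with the smallest p were LDLRAD3 (0.52), SLC48A1 (0.48) and PLXNA3 (0.32), with higher means in lactating conceptuses. NCOA7 (-0.37), C10H14orf1 (-0.27) and CCDC132 (-0.24) had lower means. None of these passed: limma called 0 of 13160 genes (smallest adjusted p = 0.907, also 0 at an adjusted p below 0.1). Without adjustment, 534 genes, 245 higher and 289 lower, had an unadjusted p below 0.05, where 658 were expected by chance. On the shrunken rlog scale, the interval of the difference lay within 1 log2 unit of 0 for 12393 genes, 94.2% of those tested. Without lactating replicate 2, in which WNT2B was 3.87, WNT2B passed with a difference of 1.58 (adjusted p = 0.0477); the count at unadjusted p was 306 without lactating replicate 1 and 857 without lactating replicate 2. MYL7 stood at 7.66 in lactating replicate 4, and its difference was 0.86 without that library.

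None of the anchor genes passed between lactating and dry conceptuses. IFNT2 differed by 0.10 (95% interval -0.55 to 0.74), PTGS2 by 0.28, PAG2 by -0.46, CDX2, a trophectoderm transcription factor, by 0.25, and MKI67, a proliferation marker, by -0.0045. The placental lactogen CSH2 differed by -0.65 with a wide interval (-2.18 to 0.88), and PAG1, a binucleate-cell glycoprotein, by -0.21. Among nutrient and growth genes, the glucose transporter SLC2A1 differed by 0.29, the cationic amino acid transporter SLC7A1 by -0.25 and the fatty acid oxidation gene CPT1A by 0.09. The lipid regulator PPARG differed by -0.13, the growth factor IGF2 by 0.38 and the hypoblast factor GATA4 by 0.18. Adjusted p values of these anchor genes were 0.907 or above in limma. ISG15, an interferon-stimulated gene, lay under the expression filter.

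Camera with a preset correlation between genes called 7 lists for lactating against dry conceptuses. With an estimated correlation none of these 7 list calls held: adjusted p = 0.582 with an estimated correlation for the other binucleate genes and adjusted p = 0.782 with an estimated correlation for the remaining 6 lists. Of 23 tested genes of cholesterol synthesis and uptake, 20 had lower means in lactating conceptuses (median -0.15, camera adjusted p = 0.000667). Among them were HMGCS1, which makes the substrate of the rate-limiting step (-0.36), the sterol feedback gene INSIG1 (-0.50) and FDFT1 (-0.29). Of 22 apoptosis and p53 target genes, 16 were lower (median -0.24, adjusted p = 0.0055), with CDKN1A, a cell cycle inhibitor, at -0.60 and GADD45A at -0.45. Of 24 genes of the unfolded protein and heat shock response, 21 were lower (median -0.09, adjusted p = 0.0055), with DNAJC3 at -0.17 and XBP1 at -0.19. Of 11 other genes of binucleate trophoblast cells, 9 were lower (median -0.33, adjusted p = 0.00792), with the oestrogen sulphotransferase SULT1E1 at -0.59 and the aromatase CYP19A1 at -0.54. In the opposite direction, 24 of 25 hypoblast and yolk sac genes were higher (median 0.38, adjusted p = 0.000955), with AFP at 1.60 (0.37 without lactating replicate 4), FGB at 1.01 and AMN at 0.46. All 8 tested genes of the embryonic disc list were higher too (median 0.16, adjusted p = 0.0353), with SALL4 at 0.19 and LIN28B at 0.33. Antioxidant genes were higher in 22 of 30 cases (median 0.09, adjusted p = 0.0498), with SRXN1 at 0.70 and HMOX1 at -0.39.

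Fry called 0 lists (smallest adjusted p = 0.230). Limma called 0 members over all genes and 0 adjusted over the list alone. At an unadjusted p below 0.05 there were 5 cholesterol, 5 apoptosis, 2 unfolded protein, 3 other binucleate, 1 hypoblast, 0 disc and 0 antioxidant genes. Lactating replicate 4 held the highest value of all libraries for 17 of 29 non-constant hypoblast genes, AFP at 9.11 among them. Without it the hypoblast median was 0.15 (adjusted p = 0.231), and with the title number as a factor it was 0.03 (adjusted p = 0.736). The unfolded protein call was lost without lactating replicate 4 (median -0.07, adjusted p = 0.156) or dry replicate 3 (median -0.04, adjusted p = 0.0898), and the call on other binucleate genes without lactating replicate 3 (median -0.29, adjusted p = 0.0895). Without lactating replicate 1 the medians of cholesterol and other binucleate genes fell to -0.07 and -0.11, with the calls kept. The disc call was lost without lactating replicate 1, 3 or 5 or dry replicate 5 or 6 (medians 0.08 to 0.18, adjusted p 0.0555 to 0.189). The antioxidant call was lost without lactating replicate 1, 3, 4 or 5 or dry replicate 1, 4, 5 or 6 (medians 0.05 to 0.13, adjusted p 0.0520 to 0.352).

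The 31 other lists were not called between lactating and dry conceptuses. Interferon tau genes had a median of 0.07 (camera adjusted p = 0.712), binucleate-clade glycoproteins -0.29 (adjusted p = 0.386), placental prolactins -0.52 (adjusted p = 0.296) and trophoblast identity genes -0.06 (adjusted p = 0.629). Nutrient lists had medians of -0.11 for amino acid transporters (adjusted p = 0.168), 0.08 for glycolysis (adjusted p = 0.131) and 0.08 for glucose and fructose transport (adjusted p = 0.199). The medians were -0.0067 for fatty acid oxidation (adjusted p = 0.976) and -0.04 for insulin and IGF signalling (adjusted p = 0.769). Interferon-stimulated genes had a median of -0.16 (adjusted p = 0.0959) and mesoderm genes 0.31 (adjusted p = 0.0631). The mesoderm score was 2.10 in lactating replicate 4 and -0.17 to 0.08 in the other lactating conceptuses, and without lactating replicate 4, dry replicate 6 and heifer replicate 4 the median was 0.07 (adjusted p = 0.999).

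**Figure D2:**
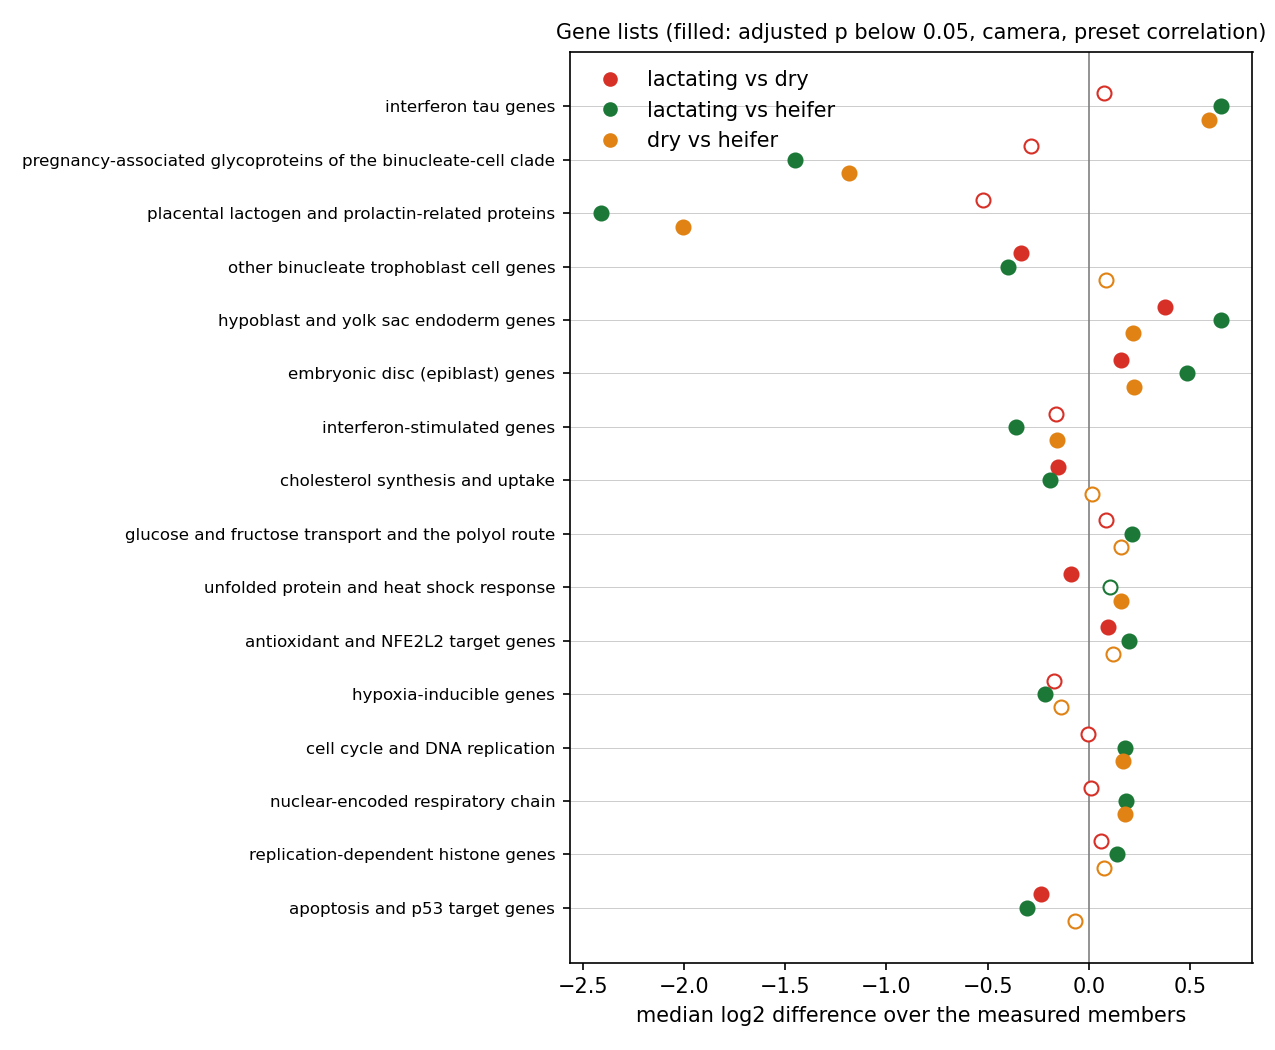
Median log2 difference (x axis) over the tested members of 16 gene lists (y axis) in each comparison; filled points are lists called by camera with the preset correlation, open points are not. Placental prolactins lie at -2.41 and -2.01 against heifers and at -0.52 between the cow groups.

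The comparison of lactating cows with heifers contrasts recipients and also the way the pregnancy was made, by embryo transfer or by insemination. Lactating conceptuses had lower means of the hormones of binucleate trophoblast cells. CSH2 averaged 5.07 ± 1.04 (SD, n = 5) in lactating and 7.73 ± 1.42 (SD, n = 4) in heifer conceptuses, a log2 difference of -2.66 with 5 of 5 lactating values under the heifer mean. The prolactin-related protein PRP4 differed by -2.95, and the glycoproteins PAG16 and PAG18 by -2.46 and -1.86. Interferon tau differed the other way, with IFNT2 at 0.65 and the related gene IFN-tau-c1 at 1.00. The smallest p values belonged to UGT1A1 (-0.73), TMEM106B (-0.42), ARID5B (-0.55), HECA (-0.83) and IRF2 (-0.78), lower in lactating conceptuses. In the other direction they belonged to WNT2B (1.804), MYL7 (1.77), CDC42EP1 (0.57), SDHAF1 (0.53) and ATXN1 (0.59). UGT1A1 averaged 5.62 ± 0.18 (SD, n = 5) against 6.35 ± 0.11 (SD, n = 4), and its 5 lactating values lay under every heifer value.

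None of these genes passed: limma called 0 of 13160 genes, with a smallest adjusted p of 0.129 shared by 225 genes. Without adjustment, 2502 genes, 1064 higher and 1438 lower, had an unadjusted p below 0.05 with 658 expected by chance. Without heifer replicate 3 that count was 1493. Without lactating replicate 2 WNT2B passed with a difference of 2.18 (adjusted p = 0.00387). RELN, an extracellular matrix protein named because it passed in alternatives, did so without lactating replicate 4 with a difference of -1.43 (adjusted p = 0.0390). With the title number as a factor, limma called RELN (-1.31, adjusted p = 0.0327) and LOC787514 (-1.09, adjusted p = 0.0386). Among the anchor genes, PTGS2 differed by 0.70 (adjusted p = 0.184), PPARG by -0.65 (adjusted p = 0.206), PAG1 by -0.88 and GATA4 by 0.74. IGF2 differed by 0.52, PAG2 by -0.48, SLC7A1 by -0.28, CDX2 by 0.21, CPT1A by 0.14 and MKI67 by 0.04. On the shrunken rlog scale, the interval lay within 1 log2 unit of 0 for 11763 genes (89.4%).

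Camera with the preset correlation called 15 lists for lactating against heifer conceptuses. None of these 15 list calls held with an estimated correlation (adjusted p = 0.5684 with an estimated correlation for each). All 5 tested placental prolactins had lower means in lactating than in heifer conceptuses (median -2.41, camera adjusted p = 0.000783), as did all 10 binucleate-clade glycoproteins (median -1.45, adjusted p = 2.23e-05). Endometrial epithelium genes went the same way without being called (median -0.36, adjusted p = 0.143). Lower too were 9 of 11 other binucleate genes (median -0.40, adjusted p = 0.0268), with the heparanase gene HPSE at -1.94 and the trophoblast transcription factor GCM1 at -1.67. The 3 interferon tau genes were higher (median 0.65, adjusted p = 0.0215). Of 60 nuclear-encoded respiratory chain genes, 57 were higher (median 0.18, adjusted p = 1.78e-06), with NDUFS7 at 0.46 and CYC1 at 0.32. Of 38 cell cycle genes, 33 were higher (median 0.18, adjusted p = 2.23e-05), with the replication licensing factor CDT1 at 0.50, as were 15 of 15 replication-dependent histones (median 0.14, adjusted p = 0.0267). Hypoblast and yolk sac genes were higher in 24 of 25 cases (median 0.65, adjusted p = 6.72e-05), with FGB at 1.91 and APOE at 1.85 and the activin antagonist FST at -2.19. The hypoblast median was 0.41 without lactating replicate 4 or heifer replicate 3, and without lactating replicate 4, dry replicate 6 and heifer replicate 4 together it was 0.375 and the call was lost (adjusted p = 0.0540). Genes of the disc list were higher in 8 of 8 cases (median 0.48, adjusted p = 0.000783), with PODXL at 1.71 and SALL4 at 0.40.

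The other 6 of these 15 calls, on metabolism, stress and interferon response, likewise did not hold with an estimated correlation. Glucose and fructose transport genes were higher in 11 of 14 cases (median 0.21, adjusted p = 0.0267), with SLC2A1 at 0.52 and SLC2A3 at 0.53 but SLC2A12 at -1.82. Antioxidant genes were higher in 24 of 30 (median 0.20, adjusted p = 0.00484), with PRDX1 at 0.54. Lower were 17 of 22 apoptosis and p53 target genes (median -0.30, adjusted p = 0.00775), with GADD45A at -0.57. So were 15 of 23 hypoxia-inducible genes (median -0.22, adjusted p = 0.0457), with the secreted glycoprotein STC1 at -2.15 and HIF1A at -0.35. Cholesterol genes were lower in 18 of 23 cases (median -0.19, adjusted p = 0.0358), with FDFT1 at -0.38. Interferon-stimulated genes were lower in 23 of 29 cases (median -0.36, adjusted p = 0.00468), with MX2 at -0.97 and RSAD2 at -0.90 (-0.47 and -0.41 without heifer replicate 4). Heifer replicate 4 held the highest value of all libraries for 29 of 46 non-constant members, and without it the median was -0.12 (adjusted p = 0.479).

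Fry called 0 lists (smallest adjusted p = 0.132), and limma called 0 members of the 15 lists over all genes. Adjusted over the list alone it called 5 prolactins, 7 binucleate-clade glycoproteins, 2 interferon tau, 2 disc, 3 hexose transport, 9 hypoxia and 1 cell cycle gene, and 0 in the other 8 lists, where 1 to 12 members had an unadjusted p below 0.05. Calls were also lost for interferon tau without heifer replicate 2 (median 0.53, adjusted p = 0.0762) and other binucleate genes without lactating replicate 3 (median -0.34, adjusted p = 0.0834). So were those on histones without lactating replicate 4 or heifer replicate 1 (medians 0.12 and 0.09, adjusted p 0.101 and 0.291), and hexose transport without lactating replicate 4 or heifer replicate 3 or 4 (medians 0.17 to 0.18, adjusted p 0.0529 to 0.108). The cholesterol call was lost without lactating replicate 1 or 3, dry replicate 6 or heifer replicate 2 or 3 (adjusted p 0.0521 to 0.211), with a median of -0.08 without lactating replicate 1 and -0.19 to -0.14 without the others. The hypoxia call was lost without lactating replicate 1, 2 or 5, dry replicate 6 or 7 or heifer replicate 1 or 2 (adjusted p 0.0503 to 0.172), with a median of -0.13 without lactating replicate 1 and -0.28 to -0.19 without the others. With the title number as a factor 4 calls were lost. The medians of hypoblast and hexose transport genes fell to 0.24 and 0.10 (adjusted p = 0.136 and 0.273), while those of antioxidant and histone genes were 0.21 and 0.17, no smaller than before (adjusted p = 0.1196 for both).

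**Figure D3:**
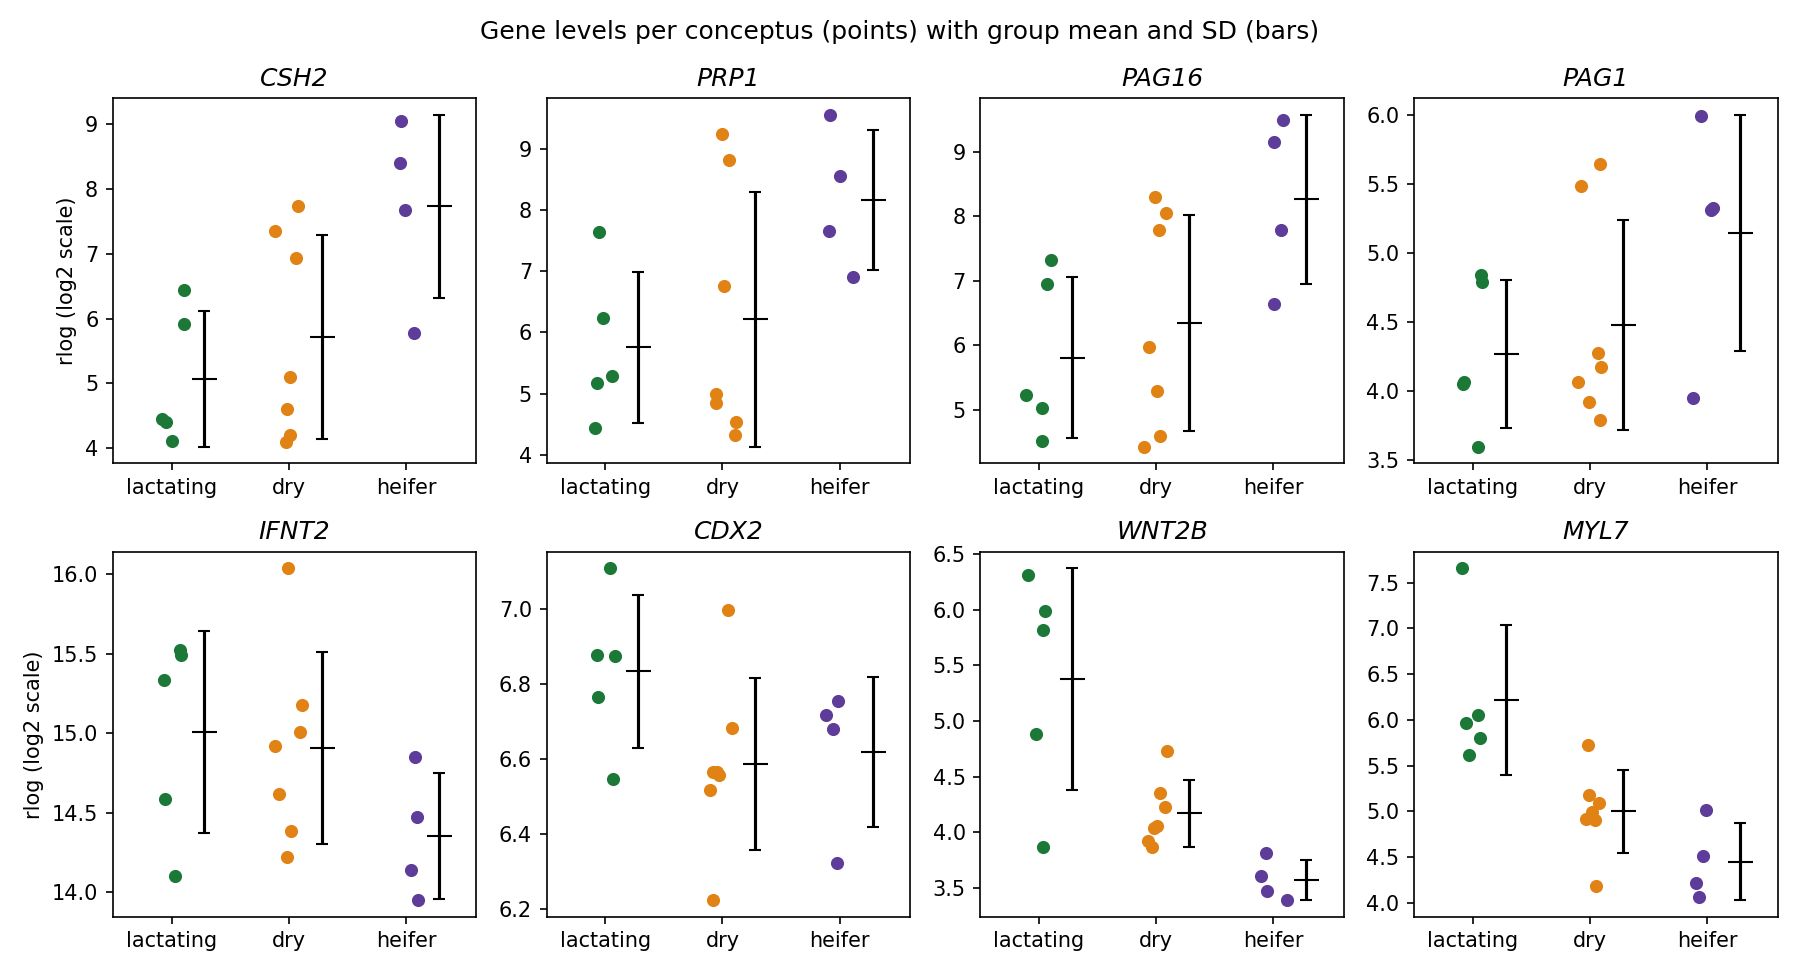
Level of 8 genes (y axis, rlog, log2 scale) in each of 5 lactating, 7 dry and 4 heifer conceptuses (points), with the group mean and SD (bars). CSH2, PRP1, PAG16 and PAG1 have their highest means in heifers and IFNT2 its lowest, and WNT2B and MYL7 are highest in lactating conceptuses.

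Dry cows against heifers share the contrast of embryo transfer with insemination, without lactation. Placental hormones had lower means in dry conceptuses, and none of them passed. CSH2 averaged 5.72 ± 1.57 (SD, n = 7) in dry and 7.73 ± 1.42 (SD, n = 4) in heifer conceptuses, a log2 difference of -2.01, with 6 of 7 dry values under the heifer mean. PRP4 differed by -2.16, PAG3 by -1.14 and PAG6 by -0.77. The interferon tau genes IFNT and IFN-tau-c1 differed by 0.59 and 0.93, and all 7 dry values of IFNT lay above every heifer value. The smallest p values belonged to ARHGEF12 (-0.33), SPG20 (-0.31), SIPA1L3 (-0.41), HOXC6 (-0.65) and GAREM (-0.36), lower in dry conceptuses. In the other direction they belonged to PLEKHH2 (0.61), the mitochondrial ribosomal protein MRPL37 (0.37), the chaperonin subunit CCT7 (0.30), DPH6 (0.49) and GRK5 (0.59). ARHGEF12 averaged 10.3 ± 0.09 (SD, n = 7) against 10.6 ± 0.09 (SD, n = 4).

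None of these genes passed: limma called 0 of 13160 genes (smallest adjusted p = 0.511, shared by 579 genes). Without adjustment, 1203 genes, 409 higher and 794 lower, had an unadjusted p below 0.05 with 658 expected by chance. That count was 558 without heifer replicate 3 and 2019 with sample weights. Anchor genes differed by 0.56 for IFNT2, 0.42 for PTGS2, -0.67 for PAG1, -0.02 for PAG2, -0.03 for CDX2 and 0.57 for GATA4. They differed by 0.22 for SLC2A1, -0.03 for SLC7A1, -0.52 for PPARG, 0.05 for CPT1A, 0.14 for IGF2 and 0.04 for MKI67. On the shrunken rlog scale, the interval lay within 1 log2 unit of 0 for 12115 genes (92.1%).

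Camera with the preset correlation called 9 lists for dry against heifer conceptuses. With an estimated correlation none of these 9 list calls held: adjusted p = 0.746 with an estimated correlation for prolactins, glycoproteins, interferon tau and cell cycle genes. It was adjusted p = 0.762 with an estimated correlation for respiratory chain, unfolded protein and disc genes, and adjusted p = 0.789 with an estimated correlation for hypoblast and interferon-stimulated genes. All 5 placental prolactins (median -2.01, camera adjusted p = 0.000462) and all 10 binucleate-clade glycoproteins (median -1.18, adjusted p = 7.66e-07) had lower means in dry than in heifer conceptuses. The score of the endometrial epithelium list went the same way without passing (difference -0.42, exact permutation adjusted p = 0.461). The 3 interferon tau genes had higher means (median 0.59, camera adjusted p = 0.0104). Higher were also 58 of 60 respiratory chain genes (median 0.18, adjusted p = 6.77e-10), with NDUFV1 at 0.30. Cell cycle genes were higher in 34 of 38 cases (median 0.17, adjusted p = 2.32e-09), with the mitotic kinase PLK1 at 0.30 and CCNB1 at 0.29. The respiratory chain gene COX7C differed by 2.00, but its values lay either at 4.21 to 4.54 or at 6.79 to 7.84 in single libraries of every group, heifer replicate 4 and dry replicate 7 each away from its group. Unfolded protein and heat shock genes were higher in 20 of 24 cases (median 0.16, adjusted p = 0.0134), with the chaperones DNAJB1 at 0.98 and HSPA1A at 0.87. SEL1L and EDEM1, also among the members with the smallest p, were lower in dry conceptuses. All 7 dry values of SEL1L lay under every heifer value, and all 7 of EDEM1 under the heifer mean. Disc genes were higher in 7 of 8 cases (median 0.22, adjusted p = 0.0134), with TDGF1 at 0.79, and hypoblast genes in 21 of 25 (median 0.22, adjusted p = 0.0251), with APOA1 at 1.55 and FOXA1 at 0.41. Interferon-stimulated genes were lower in 21 of 29 cases (median -0.16, adjusted p = 0.0334), with IFIH1 at -0.59, and without heifer replicate 4 their median was 0.0624 (adjusted p = 0.674).

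Fry called 0 lists (smallest adjusted p = 0.469). Limma called 0 members of the 9 lists over all genes; adjusted over the list alone it called 3 prolactins, 1 binucleate-clade glycoprotein and 2 interferon tau genes, and 0 in the other 6 lists, where 1 to 13 members had an unadjusted p below 0.05. Calls were lost for interferon tau without heifer replicate 2 (median 0.47, adjusted p = 0.0583) and unfolded protein genes without dry replicate 3 or heifer replicate 4 (medians 0.10 and 0.14, adjusted p 0.0612 and 0.0578). They were lost for disc genes without heifer replicate 3 or 4 (medians 0.14 and 0.21, adjusted p 0.134 and 0.0587) and hypoblast genes without dry replicate 2, 5 or 7 or heifer replicate 3 or 4 (medians 0.14 to 0.24, adjusted p 0.0593 to 0.596). The interferon-stimulated call was also lost without dry replicate 3, 5 or 7 or heifer replicate 1 (medians -0.19 to -0.08, adjusted p 0.0552 to 0.162). With the title number as a factor those on unfolded protein (median 0.11, adjusted p = 0.101) and hypoblast genes (median 0.16, adjusted p = 0.139) were lost.

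The combined binucleate score of glycoproteins and prolactins, formed after the values of both lists were seen, was 1.19 ± 0.88 (SD, n = 4) in heifer, -0.24 ± 1.18 (SD, n = 7) in dry and -0.61 ± 0.98 (SD, n = 5) in lactating conceptuses. Lactating and heifer scores differed by -1.796 (exact permutation p = 0.0476) and dry and heifer scores by -1.43 (exact permutation p = 0.0758). All p values of this combined score are of a score chosen for its difference. The scores of the separate prolactin and glycoprotein lists had exact permutation adjusted p of 0.268 for both for lactating against heifer and of 0.428 and 0.422 for dry against heifer. Sample titles open with a number whose meaning is not given by the labels, and 3 of the 6 numbers are shared by cow and heifer conceptuses. Within them the cow minus heifer difference of this score was -1.79 for number 3, -1.21 for number 7 and -1.86 for number 9. A regression within these numbers gave a common difference of -1.69 (stratified exact permutation p = 0.0222), beside a pooled difference of -1.58. For the interferon tau score the cow minus heifer differences within numbers 3, 7 and 9 were 1.07, -0.13 and 0.79.

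**Figure D4:**
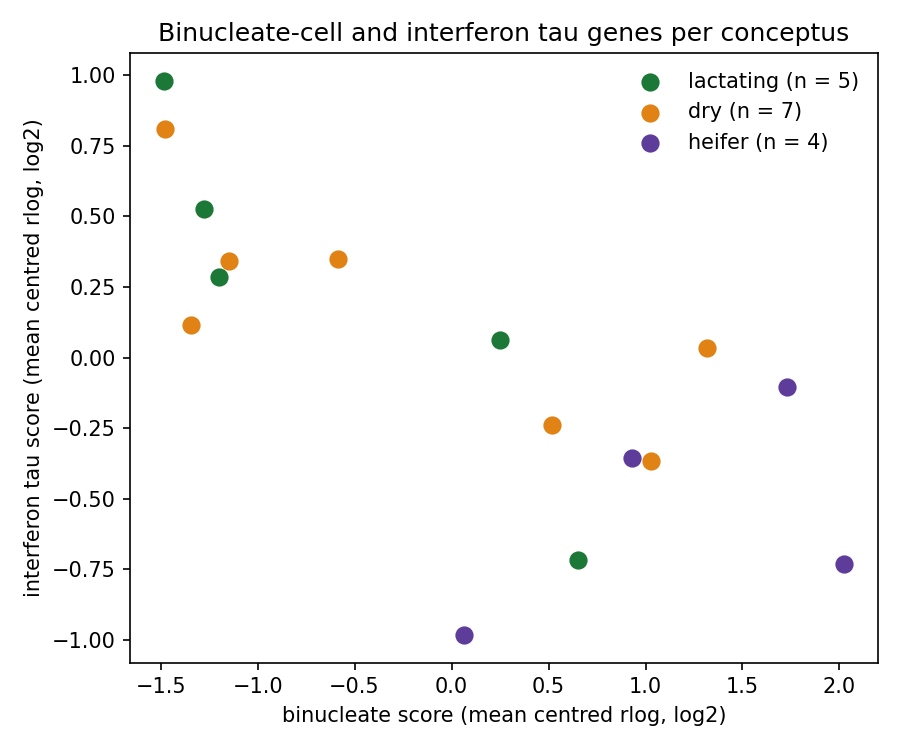
Interferon tau score (y axis) against the combined binucleate score (x axis), both as mean centred rlog values on a log2 scale, with each of the 16 conceptuses a point coloured by group. Mean binucleate scores are 1.19 in heifer, -0.24 in dry and -0.61 in lactating conceptuses.

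Both comparisons with heifers use the same 4 heifer libraries. Across the 13160 genes, which are not independent replicates, lactating minus heifer and dry minus heifer differences had a Pearson correlation of 0.839 and a covariance of 0.0726, and 78.6% of genes had the same sign. In 100 simulated sets of unchanged groups, the residuals of all 16 libraries were shuffled over the group labels. Both simulated comparisons thus shared 4 drawn libraries in the place of the heifers. Their mean correlation was 0.578 (quantiles 0.227 to 0.822) and the mean covariance 0.0285 (lowest to highest -0.0018 to 0.0622), with 70.2% of genes of the same sign. The quantiles leave out the most extreme sets at each end, so some simulated correlations lay above 0.822. Whether any reached 0.839 was not recorded. With the heifers split so that each comparison had its own pair, in 6 ways, the correlation was 0.228 to 0.533 and the covariance 0.0269 to 0.0566.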

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

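The 4 tests of explanations in this part were chosen only after the results were seen, and each value below is of a conceptus that lay far from the rest of its group, a rule that chance meets in about 26.55 of the 531 groups of values examined; 36 met it.

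Dry replicate 6 accounted for 13 of the 36. It held the highest value of all libraries for 5480 of 28573 non-constant genes, against 1026 to 1718 in the other dry conceptuses and 6.25% of genes by chance, and 309 genes lay more than 1 log2 unit above every other library. Its distance to the rest of its group was 61.9 (31.5 to 43.2 in the others), its mean correlation with other libraries 0.969 and the median of its genes under the filter -0.0630. In this library AFP was 3.60, APOA1 9.66, GATA4 5.15, PODXL 8.83, TDGF1 5.58, CDT1 6.93, SLC2A3 13.0 and SRXN1 5.44, and the score of the disc list -0.40. XIST lay at 10.3 there, between the levels of the other libraries with and without Y-linked expression. A library with Y-linked expression and raised XIST raises the question of a mixed sample, with RNA of another conceptus or of maternal tissue. This was not tested, and the values of this library in the dry group carry that doubt.

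Lactating replicate 4 had AFP at 9.11, MYL7 at 7.66 and NQO1 at 7.68, with a mesoderm list score of 2.10 against -0.17 to 0.08 in the other lactating conceptuses. In it 26 genes lay more than 1 log2 unit above every other library; among them, chosen after their values were seen, COL1A1 was 9.95, COL3A1 8.79, LUM 8.65 and DCN 8.42, and the plasma protein genes SERPINA1 9.52 and APOB 9.90. Endometrial stroma or immune cells cannot be told apart from other sources: of 18 stroma and immune list members outside the pattern only HOXA13, CD14, CD68 and CSF1R passed the expression filter (median difference -0.24 from the other lactating conceptuses, -0.47 to 0.69), and the others lay under it, where rlog values are most strongly shrunken. Embryonic or extraembryonic mesoderm, or remains of the disc, may be present, but cannot be told apart either: 5 of 26 mesoderm list members outside the pattern were highest in this library, above the share by chance and short of what was set as decisive. Of these 5 only KDR, at 6.17, passed the expression filter. FOXF1 at 3.77, SNAI2 at 3.65, TEK and HBZ lay under it on their means, as most of the stroma and immune members did. Hypoblast or yolk sac cells were not among the explanations tested. Of 25 hypoblast and yolk sac list members outside the pattern, 13 were highest in this library (median difference 0.57 from the other lactating conceptuses). Of 16 disc list members, 1 was highest there (median difference -0.03), and only 8 disc genes passed the expression filter. No biological explanation was tested beyond endometrial stroma or immune cells and mesoderm.

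Heifer replicate 4 had UBA7 at 5.30, COX7C at 6.79, TMEM106B at 9.39 and a hypoxia list score of 0.0066. Interferon-stimulated genes were high in it, with MX1 at 7.75, IFI6 at 8.04, MX2 at 5.30 and RSAD2 at 5.37. Their means were 4.81, 4.51, 3.05 and 3.18 in the 13 libraries other than lactating replicate 4, dry replicate 6 and heifer replicate 4. Endometrial epithelium may contribute, since 7 of 16 list members were highest there, among them SERPINA14 at 6.48, PAX8 at 5.85 and MUC1 at 9.21, which passed the expression filter. The rest of the 7, ESR1 at 3.02, LTF, PIGR and TFF3, lay under the filter, and TFF3 (-3.84) was near the lowest value measured, so the count overstates the evidence. PGR, OXTR and SPP1 were not highest there. At 7 of 16 the count lay between the bounds set for and against, so this source cannot be told apart from others. A higher output of interferon tau is argued against as the cause: 11 libraries had a higher interferon tau score than this one (-0.36), and the highest interferon-stimulated score among them was 0.24 (mean -0.0642, SD 0.17), against 1.02 in this library.

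Among the remaining values, AMN was 4.30 and CDX2 6.32 in heifer replicate 1, while SC5D was 8.95, the trophoblast identity score 0.10 and the Y-linked score 2.54 in heifer replicate 2, the only heifer conceptus with Y-linked expression. Heifer replicate 3 had ARHGEF12 at 10.7 and CCDC132 at 9.52. In lactating conceptuses, IDI1 was 9.11 and the fatty acid oxidation score -0.22 in replicate 1, and PODXL was 10.9 in replicate 3. In dry conceptuses, TMEM106B was 9.03 in replicate 1, HMOX1 9.24 in replicate 2, NQO1 6.52 in replicate 5, and COX7C 4.31 and UBA7 3.55 in replicate 7.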

How the results depend on the processing

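The removal of libraries that stood apart and the exact permutation of list scores, and the counts at unadjusted p, were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because replicate numbers follow the order of the records and pair no conceptuses; the title number, whose meaning is not given, was fitted as a factor. Counts of genes called stayed at 0 except for 2 genes between lactating and heifer conceptuses with the title number as a factor (RELN and LOC787514) and 1 with the libraries that stood apart removed (RELN, -1.53); leaving out a conceptus gave 0 to 1 genes for lactating against dry, lactating against heifer and the F test, and 0 for dry against heifer. Counts at unadjusted p for lactating against dry were 995 without a filter and 353 with a mean of at least 6, which tests fewer genes, and 306 to 857 with a conceptus left out; dry against heifer had 2019 with sample weights and 558 to 1759 with a conceptus left out. With a conceptus left out, lactating against heifer had 1493 to 2997 and the F test 757 to 2043. Lists called were 4 for lactating against dry and 8 for lactating against heifer with a mean of at least 6, 0 in each comparison with an estimated correlation, and 0 in each by exact permutation of list scores, where 1, 5 and 3 lists had an unadjusted p below 0.05. The last 0 is largely set by the design against heifers: the smallest p possible there is 0.00794 and 0.00303, so that over 38 lists 7 and 3 lists would have to reach it together. With a conceptus left out they were 4 to 11 for lactating against dry (4 without lactating replicate 3 or 4, 11 without lactating replicate 1 or dry replicate 7), 13 to 16 for lactating against heifer and 7 to 13 for dry against heifer. The interferon-stimulated list of dry against heifer turned direction without heifer replicate 4 (median 0.0624, within -0.29 to 0.0624 with a conceptus left out) and with the libraries that stood apart removed (median -0.0176, with camera's direction turned), so that call rests on heifer replicate 4. With the libraries that stood apart removed, 5, 13 and 10 lists were called in the 3 comparisons; lost were hypoblast genes in each (adjusted p 0.638, 0.0540 and 0.0513), disc (0.0597) and antioxidant genes (0.451) for lactating against dry, and interferon-stimulated (0.640), hexose transport (0.2496) and histone genes (0.139) for lactating against heifer. Gained by that removal were ribosomal protein genes (0.0109) for lactating against dry, and amino acid transport (0.0337) and insulin and IGF signalling genes (0.0118) for lactating against heifer. For dry against heifer, insulin and IGF signalling (0.0395), hypoxia (0.0218) and antioxidant genes (0.0401) were gained. None of the gained calls held with an estimated correlation (camera adjusted p 0.486 to 0.984). For the other changes, the cause was not tested.

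Calls on group separation and spread were the same under every alternative run. Over 22 alternatives (median centring, quantile normalisation, sample weights, title number, sex covariate, each conceptus left out, and the libraries that stood apart removed), 4087 of 4092 values of named genes did not newly pass and moved by less than the gene's SD within groups. Of the rest, 2 passed (WNT2B in both lactating comparisons without lactating replicate 2) and 3 moved by more than that SD. The sign was opposite in 38 values. No named gene was called in the main fit, so none could lose a call. An SD between conceptuses is also a wide limit for a change of a group difference, so the count of 4087 says little about stability. For the 31 list calls a mean of at least 6, camera on ranks and the estimated correlation were added, which makes 25: of 773 values 654 kept direction and call, 117 kept direction and lost the call, 31 of them with the estimated correlation, and 2 turned. No list call was kept with the estimated correlation. Kept in the other 24 were the calls on prolactins and binucleate-clade glycoproteins (medians -3.06 to -2.08 and -1.96 to -1.22 for lactating against heifer, -2.41 to -1.57 and -1.59 to -0.97 for dry against heifer), cell cycle and respiratory chain genes in both comparisons with heifers, disc genes for lactating against heifer, apoptosis genes for lactating against dry and against heifer, and cholesterol genes for lactating against dry (-0.20 to -0.07). List calls were also lost with quantile normalisation for disc and antioxidant genes of lactating against dry (adjusted p = 0.0607 for both) and unfolded protein genes of dry against heifer (0.104), with sample weights for disc (0.0814), hypoxia (0.111) and interferon-stimulated genes (0.0777), with the sex covariate for hypoxia (0.0538) and interferon-stimulated genes (0.0902), with the title number for antioxidant genes of lactating against dry (0.395), and with camera on ranks for hypoxia genes (0.0718). A mean of at least 6 ended 3, 6 and 1 calls in the 3 comparisons (adjusted p 0.0517 to 0.778) and left too few interferon tau genes to test. Depth is unknown, so what it limits was not measured.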

Other observations

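The 3 tests of explanations for the heifer contrast, the correlations between scores, the removal of libraries that stood apart, the make-up of 1 split and the pooled comparison of cows with heifers were chosen only after the results were seen; counts over other splits were planned for genes and lists called, and those at unadjusted p were added after no gene was called.

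Several lists outside the calls held further values. The ancient-clade glycoproteins, which include PAG2, had medians of -0.46, -0.48 and -0.0227 for lactating against dry, lactating against heifer and dry against heifer, with camera adjusted p of 0.131, 0.335 and 0.917. Trophoblast Kunitz domain proteins, secreted by ruminant trophoblast, had medians of -0.36, -0.28 and 0.08, the last with a mean of -0.12. Endometrial epithelium genes had medians of -0.26, -0.36 and -0.45, with camera adjusted p of 0.587, 0.143 and 0.194. Cytosolic ribosomal proteins, a list read as a check of RNA quality, had medians of -0.0075, 0.02 and 0.03; with the libraries that stood apart removed the list was called lower in lactating than in dry conceptuses (median -0.091, camera adjusted p = 0.0109 with the preset correlation and 0.984 with an estimated correlation). Y-linked genes had medians of -0.07, 0.70 and 0.74, with 2 of 5 lactating, 3 of 7 dry and 1 of 4 heifer conceptuses expressing them. Over all 12 cow conceptuses against the 4 heifer conceptuses, limma called 0 genes (smallest adjusted p = 0.145), with 2219 at an unadjusted p below 0.05, and camera called 13 lists with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.612). Exact permutation of list scores called 0 (smallest adjusted p = 0.153).

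Placental prolactin and binucleate-clade glycoprotein genes were lower, and interferon tau genes higher, in cow than in heifer conceptuses, a difference that did not pass as a list score (exact permutation adjusted p = 0.153 for each of the 3 lists). A batch shared by samples of the same title number is argued against for the binucleate genes only within limits, since within title numbers the difference was -1.69. The score was chosen for its difference. Number 7 held only dry replicate 6 and heifer replicate 3, and the only heifer library of number 9 was heifer replicate 4. Dry replicate 6 and heifer replicate 4 stood apart. Within number 3, where no library stood apart, the difference was -1.79 with 4 cow and 2 heifer libraries. Even there dry replicate 5 (1.03) lay above heifer replicate 2 (0.065). A larger share of trophoblast in the heifer libraries is argued against for the binucleate genes as well. It would lower trophoblast identity genes in cows about as much as the binucleate score (-1.58). The median difference of the trophoblast identity genes was -0.0245 (SD 0.34 over 19 genes, 11 of them lower). A candidate explanation is that conceptuses stood at different points of trophoblast differentiation: among the 12 cow conceptuses alone the scores were correlated with r = -0.789 (permutation p = 0.00169, adjusted p = 0.00507 over 12 relations) and Spearman's rho = -0.853 (permutation p = 0.00078, adjusted p = 0.00234), and r was -0.845 without the 2 farthest conceptuses. In the 7 dry conceptuses r was -0.769 (exact permutation p = 0.0448, adjusted p = 0.0896). Of the endometrial epithelium list, 7 genes were tested, while PGR, OXTR, ESR1, LTF and PIGR lay under the expression filter. The tested endometrial epithelium genes moved with the binucleate genes: their score was 0.49 lower in cows (exact permutation p = 0.0456, adjusted p = 0.193) and was correlated with the binucleate score among the 12 cow conceptuses (r = 0.905, permutation p = 0.00029, adjusted p = 0.00174). Whether attached endometrium or expression of these genes in the trophoblast lies behind that relation stays open, as do embryo transfer, recipient and the age of the conceptus, which were not tested.

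Chance could not be excluded for counts at unadjusted p or for lists called by regrouping the samples into groups of the same sizes, 100 splits for each count with the real split included. For genes called the real count was 0, which all 100 splits reach, so nothing follows from it; the highest count in another split was 1 for each contrast and 323 for the F test. Counts at unadjusted p as large as the real 534, 2502, 1203 and 1626 (lactating against dry, lactating against heifer, dry against heifer and F test) came in 57, 5, 9 and 8 splits, with highest counts of 2067, 3047, 2044 and 3137 in other splits. Lists called as often as the real 7, 15 and 9 came in 51, 13 and 39 splits, with highest counts of 18, 18 and 14. Of the other splits of all samples, 5 had genes called by the F test, and only the one with the most was examined. This split had 323 genes called against the real 0. It was picked for its count out of random regroupings, so the count alone cannot show a structure of the samples. Its group of 4, lactating replicates 1 and 5 and dry replicates 3 and 4, held the 4 lowest combined binucleate scores of all 16 libraries (-1.48 to -1.28, the next -1.20). Whether this overlap is more than chance was not tested, and both the split and the score were chosen after their values were seen.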
